A study of Marchantia polymorpha and Arabidopsis thaliana with 40 samples.

How the data were processed

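ATAC-seq was measured in 40 libraries of sorted nuclei, 32 from Marchantia polymorpha and 8 from Arabidopsis thaliana, in 20 groups of 2. Per the submitters' processing notes, the tools used were fastp 0.24.0, FastQC 0.11.9, Bowtie2 2.4.4, SAMtools, MACS2 2.2.7.1, bedtools, featureCounts, Subread 2.0.6 and deepTools, named without the order or settings of the steps. The genome builds, the treatment of duplicates, the filters on reads and the pooling of peaks were not given in the sources used here. The deposited values are counts, as raw reads per accessible region without normalization, in a table for the Marchantia heat libraries, a table for the Marchantia ABA libraries and a table for Arabidopsis. The sources used here do not say whether region starts count from 0 or 1, so starts are printed as the tables give them.

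Samples were grouped by the labels, and every column was matched to a sample. In the ABA table the sample titles and the column names state opposite treatments, and the contrast was fixed as column ABA minus column CK. GEO's batch label separates the heat libraries from the ABA libraries, and no comparison of treatments crosses it. Genotype differences were compared between the Marchantia tables only by setting side by side the fits made within each. A region of a table was matched to the region of the other that overlapped it by at least 50% of the shorter.

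Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1, a mean per group, TMM normalization and the quasi-likelihood F test. The filterByExpr filter removed 0 regions in each table, so every region was tested. P-values were two-sided and adjusted by Benjamini and Hochberg over all regions of a table for each contrast, with a threshold of 0.05. Contrasts were heat minus control within each genotype, mutant minus wild type at control, and interactions, the response of the mutant minus that of the wild type. SE is the absolute log2 change over the square root of F. CPM are counts scaled to the library total with TMM factors and are given as mean ± SD. Library totals ran from 19.6 to 71.2 M counts, and the median count per region and library was 423 in the Marchantia heat table, 342 in the ABA table and 175 in Arabidopsis. TMM factors were 0.828 to 1.05, 0.973 to 1.05 and 0.697 to 1.15 in the same order.

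The contrasts, the threshold, the rule for naming regions and the alternatives were fixed before the data were examined, except where stated. Named regions had a mean of at least 50 counts per library and passed the threshold, and were the 5 with the highest and the 5 with the lowest log2 change for the wild type heat responses and 3 each way elsewhere. Where a group had 0 counts, a fold was given only as a bound against a floor of 3 counts over the group. The method was tested on simulated data with 200 regions changed. The Tak-1 heat test found 93% of 2-fold and 45% of 1.5-fold changes with 6 false calls. The Col-0 heat test found 81% and 44% with 8, and the eTK interaction test 57% and 24% with 2. The Tak-1 test of the ABA table found 75% and 48% with 22. Simulated counts had 1 spread per region shared by all groups and were drawn independently for each region and library. Real replicate pairs differed unevenly, so these figures may not hold for the data.

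Alternatives were DESeq2 1.42.0 with its own size factors, total count scaling, loess offsets per library, a replicate block and leaving out each library in turn. Where this left a group with 1 library, that library was assumed to vary like the other groups. Replicate numbers were not treated as pairing the samples, since deviations from group means did not correlate over 0.1 in every pair of groups. They did in 6 of 28 in the Marchantia heat table, 0 of 6 in Arabidopsis and 15 of 28 in the ABA table, where the 2 conditions correlated at 0.185 in Tak-1, 0.304 in dko, 0.406 in hsfa1 and -0.091 in hsfb1, so sharing by replicate number stays open there. The alternative of no filter changed nothing, since the filter removed 0 regions. Relative to TMM, total count scaling moved the median log2 value of all regions to 0.14 for Tak-1 heat, to -0.16, -0.21 and -0.20 for the interactions of hsfa1, hsfb1 and dko, to 0.16, 0.26 and 0.15 for their differences at control, to -0.75 for Col-0 heat and to 0.71 for the eTK interaction.

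Sets of regions were chosen after the data were seen. They were the regions over 2-fold higher or lower with heat in hsfb1, Tak-1, Col-0 or eTK, read in other genotypes, the regions within 2 Mb of Arabidopsis centromere centres or chromosome ends, a stretch of Arabidopsis chromosome 2, the regions on Marchantia chromosomes U and V, and the tenth of regions with the highest mean CPM and the tenth with the lowest. Sets were tested with limma's camera, which compares a set with the other regions, with its preset correlation and with an estimated one, and p-values were adjusted over 80 set tests. Regions all but without counts in eTK had a mean of at least 20 counts in Col-0 control and at most 3 counts over both eTK control libraries. Ranges were matched with GenomicRanges 1.54.1 and plots drawn with matplotlib 3.10.9.

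No gene positions on the builds of the tables and no genome sequence were used, so gene lists, sequence motifs and the knocked-out genes were not analysed here. Positions were not converted between builds.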

Results

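Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 40 libraries that fell into 20 groups of 2. The liverwort Marchantia polymorpha was represented by Tak-1, the male wild type accession, by knockouts of hsfa1 and of hsfb1, and by the double knockout of both genes (dko). HSFA1 belongs to class A of the heat shock transcription factors, the class known as activators of the heat shock response, and HSFB1 to class B, whose members lack the activation domain of class A. Arabidopsis thaliana was represented by the wild type Col-0 and by eTK, a triple knockout of hsfa1a, hsfa1b and hsfa1d. Gemmalings, young Marchantia plants raised from asexual propagules, and Arabidopsis seedlings were sampled at day 7, either at 22 °C or after 1 h at 37 °C. A separate set of Marchantia gemmalings belonged to a treatment with 50 µM abscisic acid (ABA), a stress hormone, for 2 h or to its mock with 20% ethanol. The series title places the role of heat shock factors in heat-induced changes of chromatin at the centre of the study, so the questions were which regions changed with heat and whether they changed differently without the factors.

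The values were raw read counts in 40873 regions for the Marchantia heat libraries, 53390 regions for the Marchantia ABA libraries and 110628 regions for Arabidopsis. Library totals over these regions ranged from 21.2 to 71.2 M counts in the Marchantia heat table, from 32.7 to 47 M in the ABA table and from 19.6 to 38.7 M in Arabidopsis. Spearman correlations between replicates across regions were 0.986 to 0.995, 0.981 to 0.993 and 0.965 to 0.979 in the same order. The Tak-1 control pair and the Tak-1 heat pair differed most, with a chi-square per region of 24.5 and 24.2 against 2.44 to 9.49 in the other 6 pairs of that table. In the same table both dko control libraries had an excess of even counts, with shares of 0.536 and 0.564 against 0.497 to 0.508 in the other 14. The ABA libraries all had such an excess, with shares of 0.531 to 0.633. The dko heat response, its interaction and the dko difference at control all use the dko control libraries. Whether their excess bears on these results was not tested. The labels do not say whether replicates were separate plants or cultures, so p-values measured only the spread between these samples. The genome builds were not given in the sources used here and no gene positions on them were used, so each region is named by chromosome, start and end, without its gene, exon, intron or UTR.

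In Tak-1, heat opened a small number of regions strongly and closed others more weakly. The region on chromosome 6 from 23014005 to 23014289 rose from 0.497 ± 0.0092 to 10.8 ± 0.35 CPM (counts scaled to the library total with TMM factors; mean ± SD, n = 2), a log2 change of 4.44 (SE 0.27, adjusted p = 4.93e-13). A neighbourhood of chromosome 6 held 3 of the other regions with the highest changes. There, the region from 21510937 to 21511695 rose by 3.44 on the log2 scale, the one from 21511931 to 21512229 by 3.34 and the one from 22067508 to 22068782 by 3.29, the last from 3.81 ± 0.82 to 37.3 ± 3.2 CPM (n = 2). On chromosome 4, the region from 3027615 to 3027923 rose by 3.45 (SE 0.28). The regions with the lowest changes were on chromosome 5 from 5124492 to 5124642 (log2 change -2.47, SE 0.28), from 5055069 to 5055133 (-1.99) and from 7076760 to 7077110 (-1.81), on chromosome 4 from 21854435 to 21854559 (-1.83) and on chromosome 2 from 16759706 to 16759813 (-1.75). The chromosome 5 region from 7076760 to 7077110 fell from 16.2 ± 1.1 to 4.67 ± 1.7 CPM (n = 2). All 10 named regions passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

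Of the 40873 regions, 10230 changed with heat in Tak-1, 4886 higher and 5344 lower. Among those that changed over 2-fold the balance was uneven, with 1013 higher and 162 lower. With libraries scaled by total count alone the split was 7916 higher and 2067 lower, and with loess offsets 5301 and 4819. The higher side was also the larger when either Tak-1 heat library or Tak-1 control replicate 2 was left out. The count was 5631 without Tak-1 control replicate 2 and 4916 without Tak-1 heat replicate 2.

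**Figure D1:**
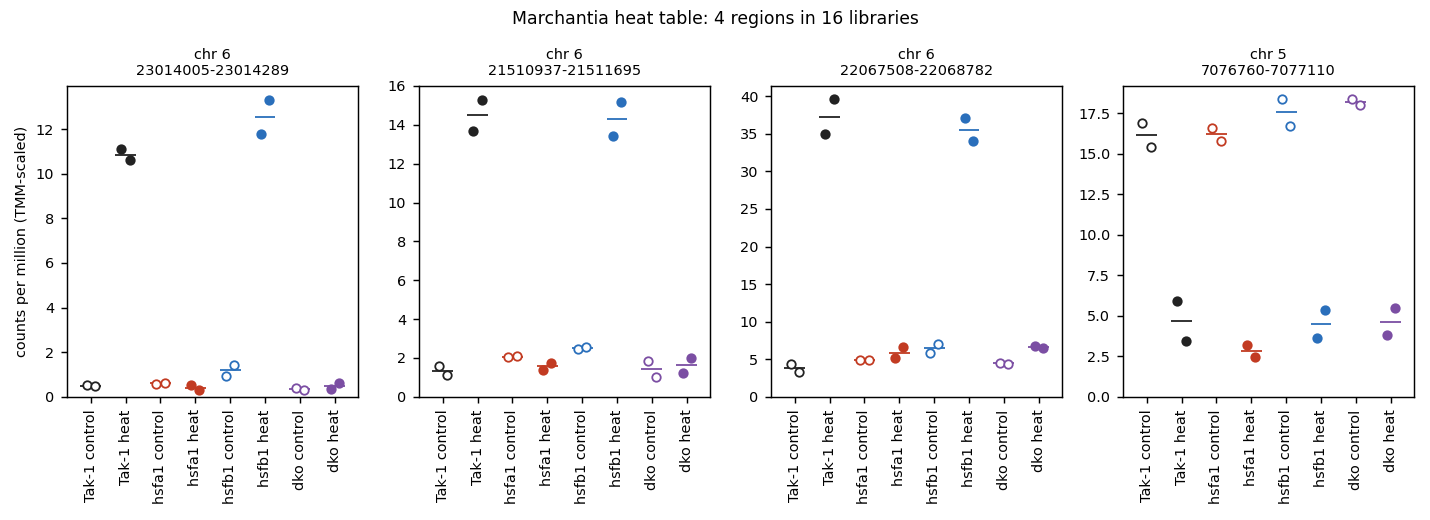
CPM (TMM-scaled, y axis) of 4 regions named for the Tak-1 heat response in all 16 libraries of the Marchantia heat table; open points are control and filled points heated libraries, and lines are means of 2. On chromosome 6 the region from 23014005 to 23014289 reached 10.8 CPM in heated Tak-1 and 12.6 CPM in heated hsfb1 but 0.396 CPM in heated hsfa1 and 0.489 CPM in heated dko, while the chromosome 5 region was lower with heat in all 4 genotypes.

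Some regions that rose in Tak-1 also rose in hsfb1, and rose less or not at all in hsfa1 and dko. In hsfb1 the region on chromosome 6 from 23014005 to 23014289 rose by 3.43 (SE 0.25, adjusted p = 1.81e-10), to 12.6 ± 1.1 CPM (n = 2). In hsfa1 its log2 change was -0.61 (adjusted p = 0.267) and in dko 0.46 (adjusted p = 0.413). The region on chromosome 6 from 22067508 to 22068782 rose by 2.47 in hsfb1 and by 0.57 in dko, and its change in hsfa1 was 0.27 (adjusted p = 0.214). The next highest in hsfb1, the region on chromosome 7 from 10377869 to 10378033, rose by 3.01 in hsfb1 and 2.90 in Tak-1, beside -0.87 in hsfa1 and -0.10 in dko, neither past the threshold, and the region on chromosome 6 from 1294093 to 1294215 rose by 2.95 in hsfb1 and 2.38 in Tak-1.

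Other regions rose in hsfa1 and dko as well as in Tak-1. On chromosome 5, the region from 6887939 to 6888745 rose by 2.69 (SE 0.21) in hsfa1, from 2.30 ± 0.11 to 14.8 ± 0.82 CPM (n = 2), by 2.2 in Tak-1, 1.31 in hsfb1 and 1.97 in dko. Beside it, the region from 6887519 to 6887743 rose by 2.43 in hsfa1 and 2.31 in dko, beside 0.52 in hsfb1 (adjusted p = 0.243), and on chromosome 7 the region from 21233392 to 21233509 rose by 2.70 in hsfa1 and by 0.89 in hsfb1. In dko the highest changes were on unplaced-scaffold_330 from 130 to 540 (3.32, SE 0.21), on chromosome 5 from 26074 to 26492 (2.85) and on chromosome 7 from 21232845 to 21232991 (2.78).

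Some regions that fell did so in several genotypes. The chromosome 5 region from 7076760 to 7077110 fell in all 4, by 1.81 in Tak-1, 2.52 in hsfa1, 1.97 in hsfb1 and 1.97 in dko. The chromosome 2 region from 8357447 to 8357526 fell by 3.40 in dko (SE 0.35), by 2.69 in hsfb1, by 2.08 in hsfa1 and by 1.47 in Tak-1. In hsfb1 the chromosome 5 region from 5124492 to 5124642 fell by 2.79 and the one on chromosome 1 from 2345744 to 2345989 by 2.59. The lowest in hsfa1 were on chromosome 8 from 7488465 to 7488669 (-2.97, SE 0.56), chromosome 1 from 26848102 to 26848220 (-2.81) and chromosome 4 from 7479071 to 7479145 (-2.68). In dko the lowest was on chromosome 4 from 11318365 to 11318976, which fell by 4.88 (SE 0.21, adjusted p = 3.81e-16), and the chromosome 2 region from 15866887 to 15867196 fell by 3.11. Both responses were lower than in Tak-1, with interactions of -5.22 and -4.5.

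In counts, 15398 regions changed with heat in hsfa1 (7016 higher, 8382 lower), 6125 in hsfb1 (2531 and 3594) and 11964 in dko (5417 and 6547). The larger side turned for hsfa1 with total count scaling (8412 higher, 6758 lower) and loess offsets (8651 and 8642), and for dko with loess offsets (7109 and 6792). It also turned for hsfb1 without hsfb1 heat replicate 2, for hsfa1 when either hsfa1 heat library was left out, and for dko without dko control replicate 1. Over 2-fold, the mutants had more lower than higher regions, with 616 higher and 1993 lower in hsfa1, 444 and 884 in hsfb1, and 757 and 1379 in dko. Across regions, which are not independent replicates, the log2 changes of pairs of genotypes correlated at Pearson's r of 0.45 to 0.63. In all 4 genotypes 698 regions were higher and 920 lower, where independent lists would share 6.9 of the higher ones. These genotypes shared no libraries. The dko response uses the dko control libraries, which stood apart in even counts. Leaving out any 1 dko library gave 6042 to 7940 regions, while the hsfa1 count was 8888 without hsfa1 control replicate 2 and 9296 without hsfa1 heat replicate 1. The hsfb1 count was 3596 without hsfb1 control replicate 2, 2908 without hsfb1 heat replicate 1 and 2257 without hsfb1 heat replicate 2.

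Whether a mutant responded differently from Tak-1 was tested as an interaction, the heat response in the mutant minus that in Tak-1. For hsfa1 the lowest interactions were on chromosome 6, at 23014005 to 23014289 (-5.04, SE 0.53, adjusted p = 2.86e-07), 21511931 to 21512229 (-4.31, SE 0.47) and 21510937 to 21511695 (-3.84, SE 0.37). The chromosome 6 region from 23014005 to 23014289 also had a lower response in dko (-3.98, SE 0.51), as did the chromosome 2 region from 15866887 to 15867196 (-4.50) and the chromosome 4 region from 11318365 to 11318976 (-5.22, SE 0.32). The highest interactions for hsfa1 were on chromosome 8 from 15989318 to 15989846 (1.39, SE 0.16), on chromosome 5 from 5128437 to 5128567 (1.53) and on chromosome 4 from 14052538 to 14052673 (1.42, adjusted p = 0.0435). The chromosome 4 region missed the threshold with total count scaling, with a replicate block and without Tak-1 control replicate 2, Tak-1 heat replicate 1 or any 1 hsfa1 library, and the chromosome 5 region missed it without Tak-1 heat replicate 1 or hsfa1 heat replicate 1. The chromosome 8 region fell by 1.03 in Tak-1, from 22.4 ± 0.14 to 11.0 ± 0.41 CPM (n = 2), and rose by 0.36 in hsfa1 and by 0.31 in dko. For dko the highest were on chromosome 2 from 4528885 to 4529039 (2.93, SE 0.46), on chromosome 8 from 144295 to 144411 (2.63) and on chromosome 7 from 2586745 to 2587262 (2.42), the last rising from 5.04 ± 0.79 to 30.0 ± 0.19 CPM (n = 2) in dko.

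For hsfb1, 4 regions had a lower heat response than in Tak-1 and 0 a higher one by edgeR. A chromosome 3 region from 4088942 to 4089704 stood out (-2.2, SE 0.25, adjusted p = 4.53e-05). It rose in Tak-1 from 5.53 ± 1.3 to 20.4 ± 0.74 CPM (n = 2), and was at 5.49 ± 0.49 CPM in control and 4.38 ± 0.18 CPM in heated hsfb1 (n = 2). Its response was also lower than in Tak-1 in hsfa1 (-2.65) and in dko (-1.73). These interactions share the Tak-1 libraries, so part of the likeness between mutants may come from them. The other regions called for hsfb1 were on chromosome 6 from 21831264 to 21831737 (-1.22, adjusted p = 0.0438), on chromosome 4 from 1846755 to 1847856 (-1.2, adjusted p = 0.0438) and, named after its values were seen, on chromosome 5 from 24607865 to 24610053 (-0.84, adjusted p = 0.0438). The chromosome 6 region fell by 1.45 in hsfb1, and its change in Tak-1 was -0.22 (adjusted p = 0.248). The chromosome 6 and chromosome 4 regions missed the threshold with total count scaling, loess offsets and a replicate block, and with a replicate block the count was 1, so the chromosome 5 region missed it as well. At an unadjusted p under 0.05 there were 6994 regions. DESeq2 called 0 and gave no adjusted p to 34074 regions, the chromosome 3, chromosome 6 and chromosome 4 regions among them. In simulated data the same test found 63% of 2-fold and 12% of 1.5-fold differences of this kind, with 7 false calls. Those 7 were a larger share of the simulated calls than the threshold of 0.05. The simulation gave all groups the same spread, while the Tak-1 pairs differed most in the data, so these figures may not hold here.

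The interaction count was 2725 for hsfa1 (1002 higher, 1723 lower), 4 for hsfb1 and 4101 for dko (1803 higher, 2298 lower). For hsfa1 the split was 375 to 1030 with total count scaling, 335 to 590 with loess offsets and 1526 to 1590 with DESeq2, and for dko it was 893 to 3436 with total count scaling, 2033 to 1833 with loess offsets and 2041 to 2081 with DESeq2. The Tak-1 control pair weighed on all 3 counts: without its replicate 1 there were 14522, 9801 and 12540 regions for hsfa1, hsfb1 and dko, of which 7946, 6242 and 6841 were higher, and without its replicate 2 there were 298, 2 and 2315. For hsfa1 the count was 383 without Tak-1 heat replicate 1, 6389 without Tak-1 heat replicate 2 and 306 to 1205 without any 1 hsfa1 library. For hsfb1 it was 490 without Tak-1 heat replicate 1, 85 without hsfb1 control replicate 1 and 1 without Tak-1 heat replicate 2 or any 1 of the other hsfb1 libraries, and for dko it was 1730 to 2674 without any 1 dko library.

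Sets of regions chosen after their values were seen, but in hsfb1 libraries alone, were read in the other genotypes. Picked by their change in hsfb1, they cannot compare hsfb1 with the other mutants. The 1013 regions over 2-fold higher with heat in Tak-1 had closer medians, of 0.64 in hsfa1, 0.87 in hsfb1 and 0.66 in dko. The 444 regions over 2-fold higher with heat in hsfb1 had a median log2 change of 1.62 in Tak-1, where 427 were called higher (adjusted p = 0.00802 by limma's camera with an estimated correlation). In hsfa1 their median was 0.44 with 178 called higher and 24 lower (adjusted p = 0.224), and in dko 0.66 with 236 higher and 15 lower (adjusted p = 0.154). The interaction over this set had a median of -1.11 in hsfa1, where 224 were called lower and 0 higher, and of -1.04 in dko, where 221 were lower and 13 higher. By camera both were lower than other regions with a preset correlation (adjusted p = 7.15e-51 and 1.69e-33), and neither call held with an estimated correlation (adjusted p = 0.0598 and 0.0898). The 884 regions over 2-fold lower in hsfb1 had medians of -0.56 in Tak-1 (402 called lower), -1.06 in hsfa1 (708 lower) and -1.12 in dko (676 lower), with adjusted p = 0.0898, 0.0655 and 0.0416 for an estimated correlation. Their interaction medians were -0.46 in hsfa1 and -0.53 in dko, with adjusted p = 0.221 and 0.200 in the same test.

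**Figure D2:**
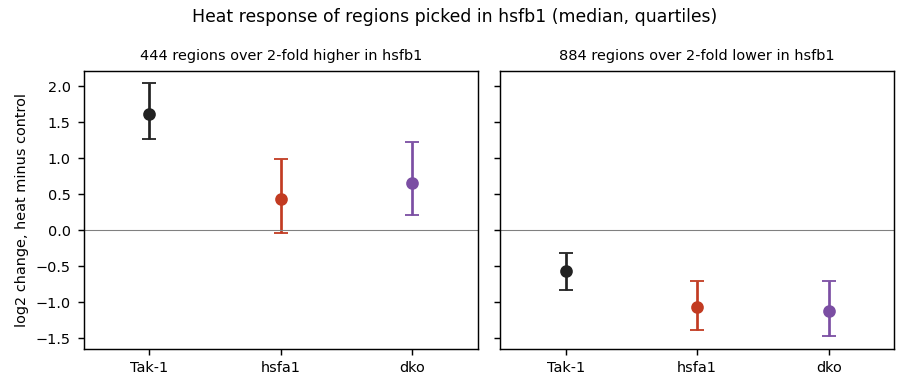
Log2 change with heat (y axis) in Tak-1, hsfa1 and dko of 444 regions over 2-fold higher (left) and 884 regions over 2-fold lower (right) in hsfb1; points are medians over regions and bars run from the lower to the upper quartile. The higher set had a median of 1.62 in Tak-1 against 0.44 in hsfa1 and 0.66 in dko, and the lower set had -0.56, -1.06 and -1.12.

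At 22 °C the mutants differed from Tak-1 at many regions, some of them all but without counts in some genotypes. Whether such regions were closed or their sequence differed between the lines was not tested. The region on chromosome 5 from 26140671 to 26140988 held 9.74 ± 1.9 CPM in Tak-1 and 0.464 ± 0.016, 0.243 ± 0.16 and 0.243 ± 0.0083 CPM in hsfa1, hsfb1 and dko (n = 2 each), with log2 differences of -4.38, -5.22 and -5.30. On chromosome 1, the region from 17091164 to 17091887 was lower in hsfa1 (-5.41, SE 0.29) and hsfb1 (-4.81, SE 0.26), and its difference in dko was -0.27 (adjusted p = 0.289). Chromosome 2 from 10184401 to 10184802 was higher in hsfb1 (5.46, SE 0.20) and dko (5.54, SE 0.20), and hsfa1 differed by -0.30 (adjusted p = 0.574). Regions higher in hsfa1 were on chromosome V from 4189335 to 4189532 (5.34), on chromosome 8 from 21310236 to 21311454 (5.31, SE 0.19) and on chromosome 2 from 25330410 to 25330496 (4.39), and the chromosome 2 region from 16067544 to 16067800 was lower (-5.92, SE 0.41). In hsfb1, chromosome 2 held the higher regions from 28546159 to 28546883 (5.80) and from 10458106 to 10458869 (5.37, from 1.25 ± 0.21 in Tak-1 to 52.2 ± 1.5 CPM, n = 2), and the chromosome 4 region from 16113525 to 16114277 was lower (-4.68, SE 0.17). In dko the regions on chromosome 2 from 15866887 to 15867196 (5.74) and on chromosome 4 from 11318365 to 11318976 (5.70, SE 0.22) were higher, and those on chromosome 5 from 9929367 to 9929767 (-5.64, SE 0.43) and on chromosome 1 from 30566694 to 30566985 (-3.86, SE 0.23) were lower. These comparisons share the Tak-1 control libraries, so part of any likeness between mutants may come from them. Those of dko also use the dko control libraries, which stood apart in even counts.

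The ABA table, whose libraries were separate, gave a second reading of genotype. In it, with the libraries in columns named CK, the chromosome 1 region from 17091174 to 17091880 again lay lower in hsfa1 (-5.74, SE 0.28) and hsfb1 (-5.70, SE 0.28), and the chromosome 2 region from 10184402 to 10184794 higher in hsfb1 (5.11, SE 0.20) and dko (5.31, SE 0.20). The chromosome 2 region from 25330410 to 25330496 did not repeat. It was higher in hsfa1, hsfb1 and dko in the heat table (4.39, 4.11 and 3.90), and its differences in the ABA table were -0.18, 0.20 and 0.35, all short of the threshold. Of 38335 regions matched between the tables by at least 50% of the shorter region, the heat table called 11249, 13691 and 5452 in hsfa1, hsfb1 and dko and the ABA table called 87, 1293 and 1056. Both tables called 30 higher and 31 lower in hsfa1, 429 and 252 in hsfb1, and 227 and 194 in dko, where independent lists would share 5 and 7, 126 and 100, and 35 and 40. A further 4, 11 and 9 were called with opposite signs. Among the regions called in the heat table, 64.6% in hsfa1, 76.8% in hsfb1 and 63.7% in dko had the same sign in the ABA table.

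Large genotype differences mostly lasted through heat. The regions read here were called at 22 °C with a difference over 8-fold and had a mean of at least 50 counts per library. Heated libraries enter that mean, so a region that keeps its counts with heat passes more easily. Of these regions, 19 of 19 in hsfa1, 49 of 49 in hsfb1 and 28 of 31 in dko were called the same way between heated libraries. The exceptions in dko were the chromosome 4 region from 11318365 to 11318976, at 48.0 ± 0.41 CPM in control and 1.61 ± 0.57 CPM in heated dko, the chromosome 7 region from 17257866 to 17258177, at 8.54 ± 6.3 and 1.58 ± 0.22 CPM, and the chromosome 2 region from 4528885 to 4529039, at 0.923 ± 0.0062 and 5.49 ± 0.30 CPM (n = 2 each). The chromosome 7 region was named after its values were seen.

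The counts of regions that differed at 22 °C moved with single libraries and with the scaling. They were 11768 in hsfa1 (5520 higher, 6248 lower), 14578 in hsfb1 (7058 and 7520) and 5810 in dko (2544 and 3266), and with total count scaling the splits were 7190 to 3605, 12432 to 3284 and 5123 to 1510. With loess offsets, which remove a trend with region density, the counts were 5910 in hsfa1 (2810 higher) and 4000 in hsfb1 (2025 higher). In the tenth of regions with the highest mean CPM, a set of 4088 chosen after the data were seen and ranked over libraries that include those compared, the medians were -0.37 in hsfa1 and -0.46 in hsfb1, with 2134 and 3162 called lower, and by camera neither call held with an estimated correlation (adjusted p = 0.221 and 0.185). Without Tak-1 control replicate 2 the counts were 140, 480 and 2189, and without its replicate 1 they were 19291, 20704 and 13700. Without hsfa1 control replicate 1 or 2 the hsfa1 count was 6766 or 562, without hsfb1 control replicate 2 the hsfb1 count was 752, and without dko control replicate 1 or 2 the dko count was 2199 or 1519.

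In the ABA libraries, the labels contradict each other. Libraries titled as mock have columns named ABA, and libraries titled as ABA have columns named CK, so the contrast was fixed as column ABA minus column CK. If the column names are right a positive value is higher with ABA, and if the titles are right it is lower with ABA. The region on chromosome 2 from 23983138 to 23983785 was lower in the columns named ABA in hsfa1 (log2 difference -0.66, SE 0.081, adjusted p = 0.00856), beside 28.1 ± 1.8 CPM (n = 2) in the columns named CK. In every genotype both libraries in columns named ABA lay below both in columns named CK at this region, such as 17.3 and 18.1 against 25.0 and 25.8 CPM in dko and 13.9 and 12.4 against 19.0 and 18.6 CPM in hsfb1. It was the 1 region called within a genotype by edgeR. The call was lost without either hsfa1 library titled mock and without hsfa1 column CK replicate 2.

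Within Tak-1, hsfb1 and dko edgeR called 0 regions of 53390, with 952, 4286 and 1951 at an unadjusted p under 0.05, and DESeq2 called 0, 1 and 3, beside 3 in hsfa1. Without hsfb1 column CK replicate 2 the hsfb1 count was 93, and without dko column ABA replicate 1 the dko count was 1. The interactions of hsfa1, hsfb1 and dko with Tak-1 called 0 regions by edgeR and by DESeq2, with 738, 2858 and 1037 at an unadjusted p under 0.05. In simulated data the Tak-1 test found 75% of 2-fold and 48% of 1.5-fold changes, with 22 false calls. Those 22 were a larger share of the simulated calls than the threshold of 0.05. With 0 calls in Tak-1, the overlap with its heat calls had no value.

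**Figure D3:**
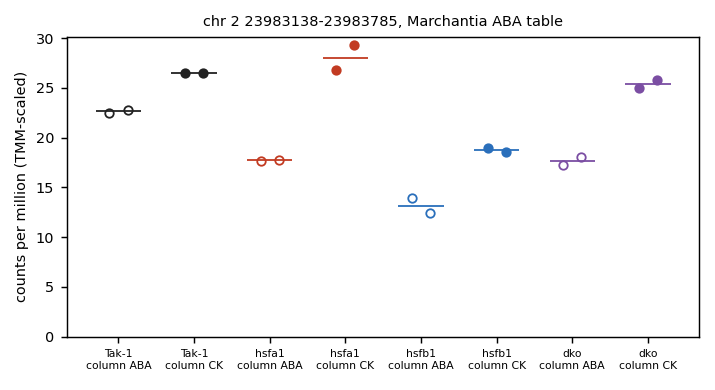
CPM (TMM-scaled, y axis) of the region on chromosome 2 from 23983138 to 23983785 in the 16 libraries of the Marchantia ABA table, by genotype and by column name; points are libraries and lines are means of 2. Libraries in columns named ABA lay below those in columns named CK in each genotype, at 13.9 and 12.4 against 19.0 and 18.6 CPM in hsfb1.

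In Arabidopsis Col-0, heated and control libraries differed at most regions. The 5 regions with the highest changes all lay in a single stretch of chromosome 2, led by 3488510 to 3488612 (4.35, SE 0.17) and 3354542 to 3354693 (4.17, from 2.48 ± 0.36 to 45.0 ± 3.8 CPM, n = 2), followed by 3466922 to 3467091 (4.15), 3404918 to 3405007 (4.14) and 3459199 to 3459330 (4.14). From 3242091 to 3509764 on that chromosome, 159 of 161 regions were higher, with a median log2 change of 3.54, while 157 regions within 100 kb on either side had a median of -1.09. The stretch took 0.689% and 0.627% of all counts in the heated Col-0 libraries and 0.0566% to 0.0954% in the other 6 libraries. Whether these counts came from opened nuclear chromatin or from reads of mitochondrial DNA that match a nuclear copy stays open.

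Outside the stretch, regions chosen after their values were seen included chromosome 5 from 21846053 to 21846389, which rose by 4.11 (SE 0.18, adjusted p = 3.36e-40) from 1.24 ± 0.19 to 21.6 ± 1.0 CPM (n = 2), and chromosome 3 from 842633 to 842948, which rose by 3.80 (SE 0.13) from 2.96 ± 0.35 to 41.3 ± 1.2 CPM (n = 2). Chromosome 4 from 17441938 to 17442156 rose by 3.92 and chromosome 5 from 3883860 to 3884066 by 3.73. The lowest were on chromosome 1 from 13885712 to 13885817 (-3.82, SE 0.54), chromosome 5 from 11470193 to 11470279 (-3.44), chromosome 4 from 3588050 to 3588126 (-3.33) and chromosome 3 from 14532281 to 14532365 (-3.20) and 13284563 to 13284635 (-3.17). Heated Col-0 held 0.136 ± 0.015 CPM at the regions on chromosomes 1, 5 and 4 (n = 2 each). At those on chromosome 3 it held 0.188 ± 0.27 and 0.262 ± 0.16 CPM (n = 2 each). Such levels rest on few counts, so the sizes of these falls are uncertain.

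Position on the chromosome went with the direction of change in Col-0. The 16091 regions within 2 Mb of the centromere centres had a median log2 change of -0.82, with 11189 lower and 1260 higher, and the 15625 regions within 2 Mb of the chromosome ends had a median of 0.45, with 8031 higher and 2521 lower. By camera both sets differed from other regions with a preset correlation (adjusted p = 4.28e-21 and 5.15e-07) but not with an estimated correlation (adjusted p = 0.0898 and 0.208). With total count scaling the medians were -1.44 and -0.17, so the sign near the ends flipped.

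**Figure D4:**
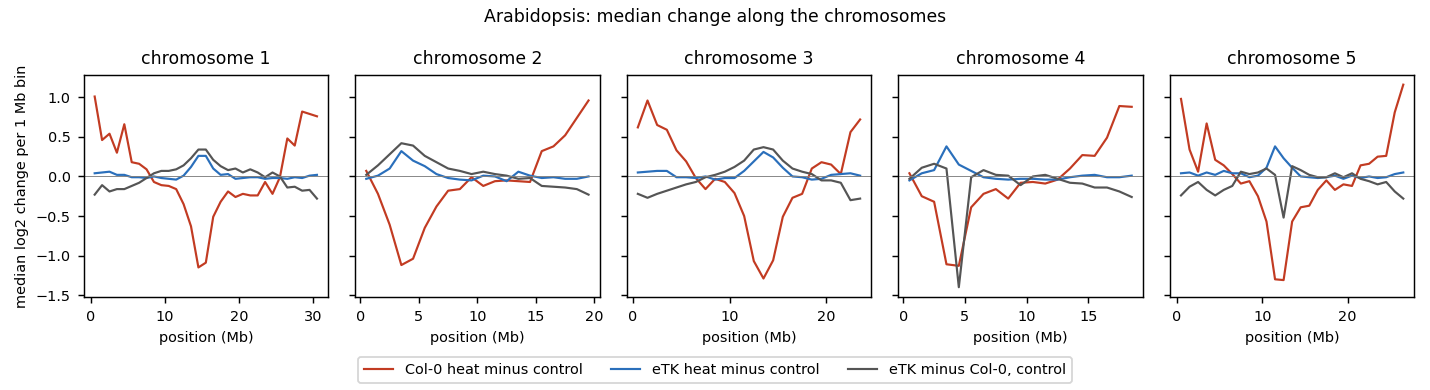
Median log2 change (y axis) of the regions in each 1 Mb bin along the 5 Arabidopsis chromosomes (x axis, Mb), for heat in Col-0, heat in eTK and the difference of eTK and Col-0 at 22 °C. In Col-0 the regions near the centromeres had a median of -0.82 and those near the ends 0.45 (-0.17 with total count scaling), against 0.18 and 0.02 in eTK.

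Of 110628 regions, 74671 differed between heated and control Col-0, 38003 higher and 36668 lower, and 25054 were over 2-fold higher and 8951 over 2-fold lower. The heated Col-0 libraries had the lowest TMM factors of the table and an excess of even counts, with shares of 0.566 and 0.557 against 0.503 to 0.509 in the other 6 libraries. With total count scaling the split was 27089 higher and 69157 lower, with the median of all regions at -0.75 in place of -0.12, and with loess offsets it was 34467 to 36679.

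In eTK, far fewer regions were called for heat, and with smaller changes. Regions with a mean of at least 50 counts over the eTK libraries were chosen after their values were seen. Heated libraries enter that mean, so a rise helps a region to pass. Chromosome 1 from 5077148 to 5077247 rose by 1.72 (SE 0.28, adjusted p = 7.1e-06) in eTK, from 0.845 ± 0.21 to 2.79 ± 0.5 CPM (n = 2), and by 1.13 in Col-0. Chromosome 3 from 4059294 to 4059405 rose by 1.42 in eTK and 2.2 in Col-0, and chromosome 3 from 22916403 to 22916487 by 1.41 and 2.60. Chromosome 2 from 19000673 to 19000793 fell by 1.34 in eTK (SE 0.20, adjusted p = 1.39e-06), from 4.14 ± 0.11 to 1.63 ± 0.33 CPM (n = 2), beside -0.33 in Col-0 (adjusted p = 0.162), and DESeq2 did not call it in eTK. Chromosome 2 from 11518427 to 11518534 fell by 1.2 in eTK, beside 0.33 in Col-0 (adjusted p = 0.0853). The other regions that the naming rule gave for eTK had at most 12 counts over both eTK libraries of either condition, so no fold is given for them. They were on chromosome 5 from 9895320 to 9895476, 14646987 to 14647068 and 12738503 to 12739294, with 0 counts in control and 10, 10 and 9 in heated eTK, and on chromosome 5 from 12432674 to 12432932 and chromosome 3 from 5440154 to 5440280, with 12 and 8 counts in control and 0 in heated eTK. Each of these calls was lost when single eTK libraries were left out.

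The heat response of eTK called 8772 regions, 4398 higher and 4374 lower, and 115 over 2-fold higher and 35 over 2-fold lower. DESeq2 called 3436 (2098 higher, 1338 lower), loess offsets gave 5418 higher and 3533 lower, and the count ran from 2417 without eTK control replicate 1 to 5341 without eTK heat replicate 1, through 3951 and 3985 without eTK control replicate 2 or heat replicate 2.

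Whether eTK responded differently was tested as the interaction, and 64977 regions differed, 28454 higher and 36523 lower. The response was lower in eTK on chromosome 3 from 842633 to 842948 (-4.18, SE 0.21, adjusted p = 8.43e-34), on chromosome 5 from 21846053 to 21846389 (-3.98, SE 0.29) and on chromosome 5 from 3883860 to 3884066 (-3.53). In eTK these regions changed by -0.38, 0.13 and 0.20, none past the threshold. It was higher in eTK on chromosome 3 from 13284563 to 13284635 (3.50, SE 0.51) and 13673173 to 13673271 (3.31), and on chromosome 2 from 3230198 to 3230269 (3.20), all lower with heat in Col-0. Heated Col-0 held 0.262 ± 0.16, 0.324 ± 0.25 and 0.46 ± 0.24 CPM there (n = 2 each), so these sizes rest on few counts. The regions given by the naming rule for this interaction had at most 9 counts over both libraries of an eTK group, namely chromosome 5 from 12738503 to 12739294, 12930097 to 12930362, 5924052 to 5924818 and 17132973 to 17133044, chromosome 4 from 4722952 to 4723256 and chromosome 1 from 27634831 to 27635120.

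The set near the centromeres had an interaction median of 1.00, with 10659 of 16091 regions higher, and the set near the ends of -0.52, with 7774 of 15625 lower (0.10 with total count scaling). With an estimated correlation the adjusted p-values were 0.0737 and 0.208, against 2.47e-28 and 5.15e-07 with a preset correlation. The chromosome 2 stretch had a median of 0.23 in eTK and an interaction median of -3.32, with 159 of 161 regions lower. By camera with an estimated correlation this interaction did not pass (adjusted p = 0.155), and the stretch was picked by its rise in heated Col-0. Of the 25054 regions over 2-fold higher in Col-0, 2249 were higher in eTK, 603 lower and 22202 not called. Of the 8951 over 2-fold lower, 181 were lower in eTK, 950 higher and 7820 not called, and Pearson's r between the responses across regions was 0.07. With total count scaling the interaction split was 61846 higher and 23919 lower.

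At 22 °C, eTK lacked reads in some regions that were well covered in Col-0. The region on chromosome 1 from 3332667 to 3333444 had 3577 counts over both Col-0 control libraries and 0 over both eTK control libraries, at least 1100-fold lower against a floor of 3 counts over the group. Chromosome 4 from 7300643 to 7301605 had 3572 and 0 counts, and chromosome 5 from 14586025 to 14586905 had 3409 and 0. Such floors cover counting error only. Among regions with a mean of at least 50 counts per library in each genotype, chosen after their values were seen, chromosome 5 from 140392 to 141989 was lower in eTK (-4.45, SE 0.10), at 50.7 ± 0.36 CPM in Col-0 and 2.32 ± 0.23 CPM in eTK (n = 2 each). Regions higher in eTK were on chromosome 5 from 11733608 to 11733690 (2.60, SE 0.25) and on chromosome 3 from 22770416 to 22770483 (2.53) and from 20121130 to 20121601 (2.49, SE 0.093), the last at 34.2 ± 0.53 against 6.08 ± 0.75 CPM (n = 2 each).

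In all, 1075 of 110618 regions with a mean of at least 20 counts in Col-0 control had at most 3 counts over both eTK control libraries. The reverse was found at 0 regions. It could hardly occur, since 110618 of all 110628 regions had such a mean in Col-0 control, so that 0 decides nothing. The 1075 regions were unevenly placed, with 42, 0, 55, 364 and 614 on chromosomes 1 to 5. Shares of the eligible regions would give 276, 185, 211, 164 and 238. Of these regions 1031, or 95.9%, had at most 3 counts over both heated eTK libraries as well. The difference of eTK and Col-0 at 22 °C called 22099 regions, 7302 higher and 14797 lower, with 3174 over 2-fold lower and 400 over 2-fold higher. The split was 12218 to 10771 with total count scaling and 1789 to 13629 with DESeq2, and the count was 11784, 12726, 14103 and 13147 without Col-0 control replicate 1, Col-0 control replicate 2, eTK control replicate 1 and eTK control replicate 2.

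**Figure D5:**
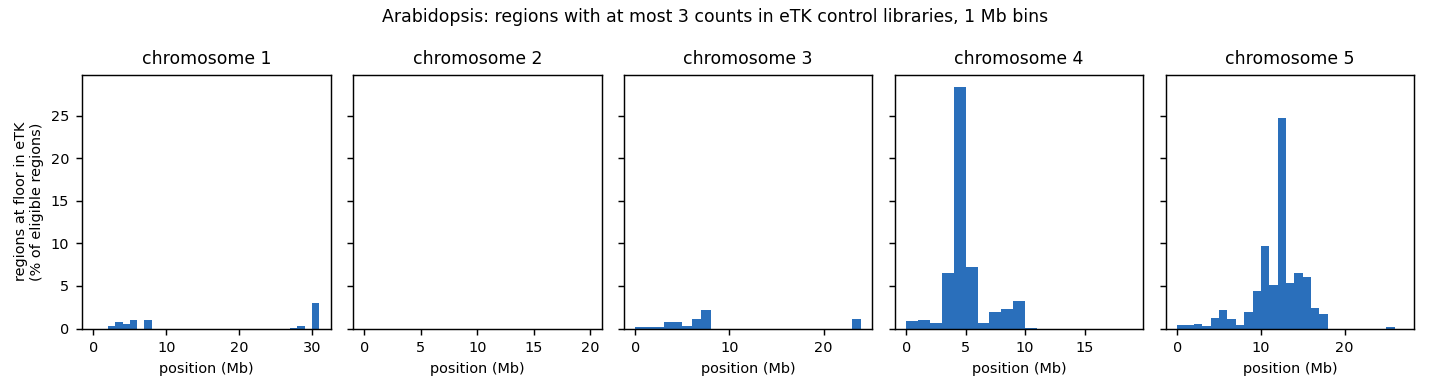
Share of eligible regions (y axis, percent) with at most 3 counts over both eTK control libraries, in 1 Mb bins along the 5 Arabidopsis chromosomes (x axis, Mb). Chromosome 2 held 0 such regions, chromosome 4 held 364 and chromosome 5 held 614.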

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

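The tests of the chromosome 2 stretch for mitochondrial reads and for opening by heat, and the tests of the regions without eTK counts for a strain variant and for a spread loss, were chosen only after the result was seen.

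A test of the difference itself called regions where the heat response of a mutant differed from that of the wild type. It called 2725 regions in hsfa1, 4 in hsfb1 and 4101 in dko against Tak-1, and 64977 regions in eTK against Col-0. For hsfb1 a replicate block left 1, and in simulated data the test made 7 false calls. That simulation had 200 regions changed, so the 7 do not say how many of the 4 hsfb1 calls are false. DESeq2 called 0, with 7031 at an unadjusted p under 0.05, but gave no adjusted p to 34074 of 40873 regions. The chromosome 3, chromosome 6 and chromosome 4 regions called by edgeR for hsfb1 were among them, so DESeq2 says little on those. In the heat table both dko control libraries, the whole of that group, stood apart in their share of even counts. The shares were 0.536 and 0.564, against 0.497 to 0.508 in the other 14 libraries. Chromosome V held 0.789% and 0.786% of their counts, against 1.68% to 2.41% in the other controls and 0.786% to 1.98% in heated libraries. In the ABA table, even shares were 0.531 to 0.633 and chromosome V held 0.441% to 0.998% of counts. These ranges include both dko control libraries, and the cause of this was not tested. The dko heat response, its interaction and the dko difference at control all use these control libraries. Whether their standing apart bears on those results was not tested. The Marchantia counts moved most with the Tak-1 control pair, and were 14522, 9801 and 12540 without its replicate 1 and 298, 2 and 2315 without its replicate 2. For hsfa1 the count was also 383 without Tak-1 heat replicate 1, 6389 without Tak-1 heat replicate 2 and 306 to 1205 without any 1 hsfa1 library. For hsfb1 it was also 490 without Tak-1 heat replicate 1, 85 without hsfb1 control replicate 1 and 1 without any 1 of the others, and for dko 1730 to 2674 without any 1 dko library. For eTK, leaving out any 1 library gave 59510 to 62817 regions. The split was 28454 higher and 36523 lower with TMM and 61846 and 23919 with total count scaling, and the count rests on the 2 heated Col-0 libraries, which stood apart in TMM factors (0.697 and 0.715, against at least 1.09 in the other 6) and in even counts.

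On Arabidopsis chromosome 2, 98.8% of the regions from 3242091 to 3509764 were higher in heated Col-0. A trend of change with region density was argued against, since the median log2 change was 3.52 with loess offsets beside 3.54 with TMM. Reads of mitochondrial DNA that match a nuclear copy and opening of nuclear chromatin by heat in the wild type both stay open. The share of 98.8% and the median interaction of -3.32 in eTK decide neither, since the stretch was picked by its rise in heated Col-0. The interquartile range of the log2 changes was 0.41 over the stretch and 0.56 over its flanks, but their SD over regions was 0.61 and 0.49. The spread thus did not decide either. The 2 explanations cannot be told apart from counts per region.

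Of the regions all but without counts in eTK control, 95.9% were so in heated eTK as well. Lower depth was argued against, since the eTK control libraries had 93% of the total count of the Col-0 control libraries. Loss of accessibility spread over the genome with the missing factors was argued against by chromosome 2, which held 0 such regions where its share would give 185. A strain variant against the reference, such as segments from another accession or deletions, may account for them, and a loss of accessibility limited to those places was not tested apart from it. Genotype and any such variant go together in every eTK library. Differences between eTK and Col-0 thus cannot be assigned to the missing factors at these regions. Segments could also hold regions with counts, so the same limit may apply to differences and interactions at neighbouring regions. On chromosome 4 from 4 to 5 Mb and chromosome 5 from 12 to 13 Mb, 28.4% and 24.7% of eligible regions were all but without counts. The counts of differences and interactions include such places. How far any segment reaches was not tested.

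Near the centromeres and near the chromosome ends, the regions of heated Col-0 moved apart, with a difference of 1.27 between the medians. A trend with region density as the whole of it was argued against by the difference of 1.1 with loess offsets. A different making of the heated Col-0 libraries could not be excluded, since these libraries had values of 1.49 and 1.54 for median log2 CPM near the ends minus near the centromeres, against at most 0.30 in the other 6. Even counts were in excess in the same 2 libraries, with shares of 0.566 and 0.557 against 0.503 to 0.509. They are the whole of the heated Col-0 group, so the making of the libraries and a response of Col-0 to heat cannot be told apart here.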

How the results depend on the processing

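The averaged ABA contrast and the medians of region sets were added with their alternatives after the result was seen. Of the 21 counts of regions, 16 stayed within 1.5-fold with DESeq2, 17 with loess offsets, 20 with a replicate block and 19 with total count scaling. The counts of the ABA table contrasts were 0 or 1, where a fold says little, and they are part of this tally. The cause of the exceptions was not tested.

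With total count scaling the exceptions were the interactions of hsfa1 (1405) and hsfb1 (2). With loess offsets they were the same interactions (925 and 2) and the differences at 22 °C of hsfa1 (5910) and hsfb1 (4000). With a replicate block the exception was the hsfb1 interaction (1). With DESeq2 they were the hsfb1 interaction (0, with 7031 at an unadjusted p under 0.05), the ABA table contrasts in hsfa1 (3), hsfb1 (1) and dko (3) and the eTK heat response (3436).

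Leaving out single libraries gave 4916 to 15234 regions for heat in Tak-1, 8888 to 11424 in hsfa1, 2257 to 4883 in hsfb1 and 6042 to 7940 in dko. The interactions ran from 298 to 14522 in hsfa1, from 1 to 9801 in hsfb1 and from 1730 to 12540 in dko, and the differences at 22 °C from 140 to 19291, from 480 to 20704 and from 1519 to 13700. The lowest and highest of these were without Tak-1 control replicate 2 and replicate 1, except for Tak-1 heat (lowest without Tak-1 heat replicate 2), the hsfa1, hsfb1 and dko responses, which hold no Tak-1 library, the lowest for the hsfb1 interaction, and the lowest for both dko contrasts (without dko heat replicate 1 and dko control replicate 2). The ABA table contrasts gave 0 to 1 in hsfa1, 0 to 93 in hsfb1 and 0 to 1 in dko, with 93 without hsfb1 column CK replicate 2 and 1 in dko without column ABA replicate 1. The eTK heat response gave 2417 to 5341, lowest without eTK control replicate 1, and the eTK difference at 22 °C 11784 to 14103, lowest without Col-0 control replicate 1. Col-0 heat, at 66628 to 68366, and the eTK interaction, at 59510 to 62817, stayed within 1.5-fold without any 1 library.

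The median near the Arabidopsis chromosome ends changed sign with total count scaling, to -0.17 for Col-0 heat and 0.10 for the eTK interaction, as that scaling lowered the values of heated Col-0, with the median of all regions at -0.75. Of 12 medians of region sets, 6 more moved past the spread between replicates with total count scaling, 8 with loess offsets, 1 with DESeq2 and 0 with a replicate block, without a change of sign. Among named regions 3 lost their call with total count scaling, 2 with loess offsets, 3 with a replicate block and 8 with DESeq2, and none changed direction under these 4 alternatives. Leaving out single libraries ended 38 of 444 calls, at 11 of the 90 regions. The 8 got no adjusted p from DESeq2, and were 3 of the hsfb1 interaction and 5 of eTK heat, among them the chromosome 2 region from 19000673 to 19000793. In data simulated at the depth of these libraries, with the same spread in all groups, 45% of 1.5-fold changes were found in Tak-1 heat. In the hsfb1 interaction 12% were found.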

Other observations

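The averaged ABA contrast and the sets by density, by sex chromosome and by change in another genotype were chosen only after the data were seen, while the test by other splits was set before its result.

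Averaged over the 4 genotypes, the contrast of column ABA minus column CK called 24 regions by edgeR, 2 higher and 22 lower, with 2929 at an unadjusted p under 0.05. The count was 14 with total count scaling, 29 with loess offsets, 36 with a replicate block and 80 by DESeq2. In simulated data the same test made 26 false calls. Those 26 were a larger share of the simulated calls than the threshold of 0.05. That simulation had 200 regions changed, so the 26 do not say how many of the 24 calls are false. The chromosome 2 region from 23983138 to 23983785 was among the 24 (-0.48, SE 0.041, adjusted p = 3.04e-05) and was lower in all 4 genotypes. Of 60 splits of the libraries within genotypes, drawn from 648 possible, 6 called as many regions, the real one included, and the highest other called 1012, so chance cannot be excluded. A split with many times the real count points to a structure of the samples, and what it is was not tested. The splits did not keep replicate numbers together. Leaving out single libraries gave 8 to 36 regions, 8 without Tak-1 column ABA replicate 2, 9 to 15 without any 1 of the others except dko column ABA replicate 2 (26), dko column CK replicate 1 (16) and hsfb1 column CK replicate 2 (36). Of 18 regions matched to the heat table, 2 were higher and 10 lower with heat in Tak-1.

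The 1013 regions over 2-fold higher with heat in Tak-1 had median log2 changes of 0.64 in hsfa1, 0.87 in hsfb1 and 0.66 in dko, with 539, 705 and 557 called higher. The 162 regions over 2-fold lower in Tak-1 had medians of -1.38, -1.31 and -1.49, with 156, 148 and 133 called lower. By limma's camera with an estimated correlation the lower set passed in each mutant (adjusted p = 0.000844, 0.000265 and 0.000844), and the higher set passed in hsfb1 (adjusted p = 0.0416) but not in hsfa1 or dko (adjusted p = 0.208 and 0.155). Picked in Tak-1, these sets are biased toward large changes there, so they were not compared with Tak-1. The 115 regions over 2-fold higher with heat in eTK had a median of 1.96 in Col-0, where 90 were called higher, and the 35 lower ones had a median of -0.24, where 14 were called lower, with adjusted p = 0.221 and 0.154. In eTK, the 25054 regions over 2-fold higher in Col-0 had a median of 0.09 and the 8951 lower ones 0.17, with adjusted p = 0.221 and 0.155.

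Regions were ranked by mean CPM over all libraries of a table, heated ones included, so a change with heat also moves a region in the ranking and these p-values are not those of sets chosen apart from the change. In Col-0 the tenth of regions with the highest mean CPM had a median log2 change of 1.16 with heat (0.53 with total count scaling, 0.27 with loess offsets, which by construction remove such a trend), and the tenth with the lowest had -0.45. With an estimated correlation the adjusted p-values were 0.0737 and 0.0235. In the eTK interaction the tenth with the highest and the tenth with the lowest had medians of -1.19 (8969 called lower) and 0.53, with adjusted p = 0.0655 and 0.0209 in the same test. In Tak-1 the tenth of regions with the highest and the one with the lowest mean CPM had medians of -0.29 and 0.10, with adjusted p = 0.396 and 0.513.

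Counts fell on both sex chromosomes in Marchantia, with 0.786% to 2.41% of counts on chromosome V and 0.0651% to 0.192% on chromosome U in the heat table, and 0.441% to 0.998% and 0.0323% to 0.0933% in the ABA table. Tak-1 is a male accession, and whether the reads counted on chromosome U came from that chromosome was not tested. The 22 regions on chromosome U had a median log2 change with heat of -0.55 in Tak-1 (21 called lower), -1.03 in hsfa1 (22 lower), -0.05 in hsfb1 (2 lower) and 0.65 in dko (16 higher), with adjusted p = 0.221, 0.154, 0.887 and 0.221 for an estimated correlation. The interaction of dko had a median of 1.22 with 21 called higher (adjusted p = 0.0898 with an estimated correlation), and at 22 °C dko had a median of -0.74 against Tak-1, with 18 called lower (adjusted p = 0.154). Both values use the dko control libraries, which stood apart in even counts and had 0.0712% and 0.0651% of counts on chromosome U. At 22 °C hsfa1 and hsfb1 had medians of 0.63 (18 called higher) and 0.26 (8 higher), and their interactions had medians of -0.45 and 0.56. None of these passed with an estimated correlation (adjusted p = 0.208, 0.569, 0.345 and 0.208). The 137 regions on chromosome V had medians with heat of 0.07 in Tak-1 (40 called higher, 36 lower), -0.35 in hsfa1 (8 and 63), -0.04 in hsfb1 (4 and 21) and 0.28 in dko (41 and 16), with adjusted p = 0.887, 0.345, 0.831 and 0.494 for an estimated correlation.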
